A study of Mus musculus with 8 samples.

How the data were processed

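Ribosome-associated RNA of lung endothelial cells was measured in 8 libraries from C57BL/6J mice, 4 from control mice in room air and 4 from mice with an induced endothelial Sox17 deletion in hypoxia. Per the labels' protocols, tagged ribosomes were immunoprecipitated from lung, RNA was purified with a column kit, and libraries were made with a QuantSeq kit, which sequences the 3′ end of polyadenylated transcripts. A 3′ tag gives about 1 fragment per transcript whatever its length, so counts were not divided by transcript length. Whether a library came from a single animal is not given in the sources used here, so p-values measure the spread between these libraries, which may be partly technical.

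The deposited values are whole-number counts per gene symbol, not normalized, with a table for each library. Per the submitters' processing notes, Bowtie2, bedtools and the mouse build mm10 were used, with no versions or settings listed. How reads with several matches, duplicate reads and strand were treated is not given in the sources used here. Such choices can change the counts of genes with near-identical copies and of overlapping genes. Gapdh, which has many processed pseudogenes, reached 12.8 ± 4.74 counts-per-million (CPM; SD, n = 4) in control libraries, so levels of multi-copy genes, including those for ribosomal and heat shock proteins, globins and myosins, are uncertain. Tsix, which is antisense to Xist, had 50.0 ± 34.6 CPM in control libraries beside 53.2 ± 33.5 CPM for Xist, and the strand of such reads cannot be told. The tables held 23238 distinct symbols after 44 duplicate rows were summed, of which 14071 had at least 1 count in any library. Mitochondrially encoded genes have no rows, so their share, a usual sign of RNA quality, was not measured.

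Library totals ranged from 7000313 to 12913304 counts, so that 3 counts, the smallest level set apart from 0, correspond to between 0.232 and 0.429 CPM of the total. No pair of libraries agreed within sampling noise: the smallest chi-square per degree of freedom between any 2 libraries was 191. No library was thus a plain repeat of another, and all 8 were kept as replicates. The measure cannot tell separate animals from separate preparations of the same RNA. Samples were grouped by the group name in their titles. The replicate numbers in those titles were not used to pair libraries, since no label says that a number is shared by anything.

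Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using trimmed mean of M values (TMM) factors, the filterByExpr filter, a model with the group alone and the quasi-likelihood F test. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. The standard error of a log2 fold change was taken as its size divided by the square root of F. CPM values use the TMM-scaled library sizes, and means are given with the SD over 4 libraries. All log2 fold changes are Sox17-deleted hypoxia minus control normoxia. Single measures per library were compared with two-sided exact permutation tests, for which 4 against 4 libraries cannot give a p below 0.0286.

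Before the data were examined, 42 gene lists were fixed: endothelial subtypes, signalling and metabolic pathways, signs of RNA quality, and markers of other lung cell types that an immunoprecipitate can carry. Lists with at least 3 tested members (35 of them) were tested with camera in edgeR at a preset inter-gene correlation of 0.01, adjusted over lists. The same lists were tested with the correlation estimated for each list and with the rotation test fry. The summed CPM of each list per library was compared with the exact permutation test, adjusted over the 42 lists. Gene positions come from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, which held 96.8% of the tested symbols.

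The rule for named genes, also fixed beforehand, took Sox17, Hgf and Met always, the 10 highest and 10 lowest fold changes among called genes, called members of called lists, and the most abundant member of each list of another cell type. Called genes had to reach 8 CPM in a group and have no overlap between the groups, and predicted genes, sex-linked genes and immunoglobulin or T cell receptor segments were left out. No gene was called, so the second part named none. In its place, the 24 genes with the lowest p among those with a mean of at least 128 CPM over all libraries are named, a choice made after the values were seen, and 1 of them is not reported here.

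The tests were run on simulated counts with 200 changed genes drawn for this comparison. With low dispersion, 82.1% of 2-fold, 100% of 4-fold and 100% of 16-fold changes were recovered among 8279 genes tested, with 8 false calls. With the dispersion observed here, 0% of 2-fold, 3.23% of 4-fold and 18.6% of 16-fold changes were recovered among 7728 genes, with 1 false call. Restricted to genes with a mean of at least 128 CPM, 7.02%, 64.2% and 100% were recovered among 1579 genes, with 3 false calls. Each simulation gave both groups the same dispersion, so recovery in the data may differ. At a mean of 32 to 128 CPM, the median SD of log2 values in the data was 0.833 in control libraries and 2.17 in Sox17-deleted hypoxic libraries. With low dispersion and genes drawn independently of each other, the camera test called the 1 shifted list and 0 of the others among 40 simulated lists. Camera was not run on simulated counts with the dispersion or the correlation between genes observed here.

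The alternatives were DESeq2 (RLE) size factors or upper-quartile factors in place of TMM, no low-count filter, a stricter filter, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom 3.58.1 with sample quality weights, and an added requirement of a doubling or halving. Chosen after seeing the data were the restriction to genes with a mean of at least 128 CPM, robust edgeR estimation, DESeq2 on the filterByExpr genes, and lists without their 2 most abundant members. Alternatives planned for normalized values were not run because the tables hold counts.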

Results

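Ribosome-bound transcripts of lung endothelium were profiled in 8 libraries, 4 from control mice kept in room air and 4 from mice with an induced endothelial deletion of Sox17 kept in hypoxia. Sox17 is a transcription factor of arterial endothelium, and variants of the human gene are linked to pulmonary arterial hypertension. Both groups carried Cdh5-CreERT2, a tamoxifen-inducible recombinase expressed in endothelial cells, and the RiboTag allele, which puts a haemagglutinin tag on the ribosomal protein RPL22 wherever the recombinase is active. Pulling down the tag enriches the ribosomes of endothelial cells, with their transcripts, from whole lung. All mice received 2 mg of tamoxifen on each of 5 days at 8 weeks of age, and the 3 weeks of room air or hypoxia began at 10 weeks. Genotype and oxygen differed together between the groups, so every difference below belongs to their combination.

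Total counts ranged from 10567561 to 11884614 in control libraries and from 7000313 to 12913304 in Sox17-deleted hypoxic libraries (exact permutation p = 0.486). Fewer genes were detected in the Sox17-deleted hypoxic libraries: 8450 ± 305 had at least 1 count, against 10081 ± 259 in the controls, with no overlap between the groups (exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow). Genes with at least 10 counts numbered 6832 ± 525 and 8767 ± 405 (exact permutation p = 0.0286). Genes with a mean of 20 to 50 CPM in the other 7 libraries had 0 or 1 count in 10.4% of cases in control libraries and 30.05% in Sox17-deleted hypoxic ones. Across genes, pairs of control libraries correlated at r = 0.83 to 0.86 and pairs of Sox17-deleted hypoxic libraries at r = 0.70 to 0.75, where genes are not independent replicates. The ribosomal RNA precursor Rn45s took 5.58% ± 2.52 and 4.67% ± 0.630 of counts (exact permutation p = 0.543).

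**Figure D1:**
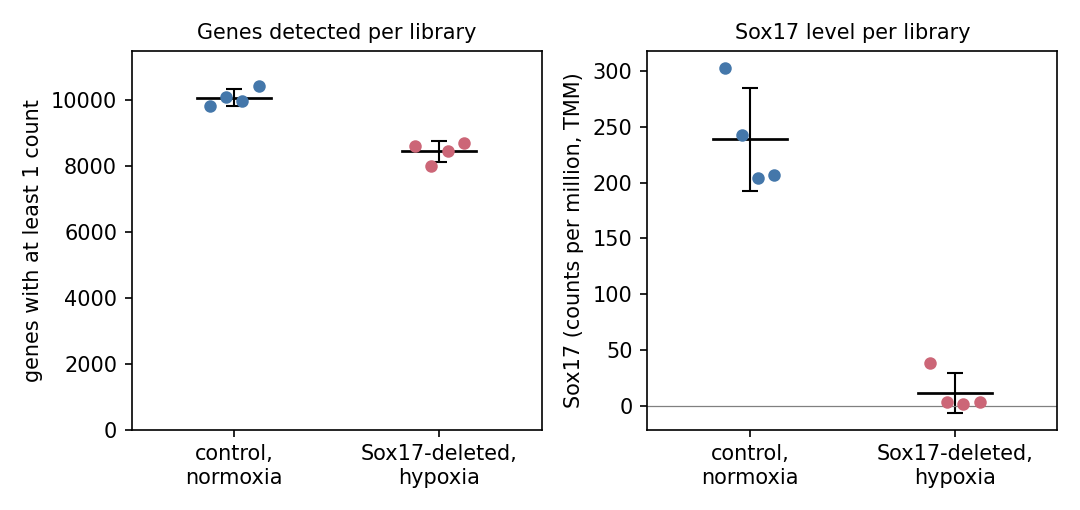
Genes with at least 1 count (left) and Sox17 in CPM (right) for each of the 8 libraries, grouped by condition; points are libraries, horizontal lines means and bars the SD (n = 4). Both measures are lower in all 4 Sox17-deleted hypoxic libraries, with Sox17 at 239 ± 46.1 against 11.4 ± 17.6 CPM.

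Sox17, the deleted gene (chromosome 1, 4490931 to 4497354, minus strand, GRCm38), had 239 ± 46.1 CPM in control libraries and 11.4 ± 17.6 CPM in Sox17-deleted hypoxic libraries (SD, n = 4). Its counts were 3072, 2591, 2442 and 2442 in the controls and 473, 31, 6 and 41 in the Sox17-deleted hypoxic libraries, lower in 4 of 4. The log2 fold change was −4.39 (SE 1.01), with an edgeR quasi-likelihood p of 0.000735 and an adjusted p of 0.346. Without Sox17-deleted hypoxic library 1, which kept 473 counts, the log2 fold change was −6.51 with an edgeR adjusted p of 0.0152. Whether the deleted part includes the 3′ end that was sequenced is not given in the labels, so a tag from a truncated transcript would still be counted. Hgf, which encodes hepatocyte growth factor, the ligand of the receptor MET, had 530 counts in Sox17-deleted hypoxic library 2 and 0 in the other 7 libraries. Met had 34, 0, 0 and 162 counts in the controls and 1, 0, 2 and 249 in the Sox17-deleted hypoxic libraries. Neither passed the expression filter, and tested without a filter the edgeR adjusted p was 0.36 for Hgf and 1.00 for Met.

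The comparison asks which transcripts of the endothelial pulldown differ when Sox17 is lost and oxygen is low, a combination used to model pulmonary hypertension. Alveolar type 2 markers summed to 1200 ± 221 CPM in controls and 2944 ± 838 CPM in Sox17-deleted hypoxic libraries. Fibroblast markers summed to 964 ± 144 and 3775 ± 4021 CPM. The higher levels given here and in the next paragraph may therefore not be endothelial, which was not tested. The chemokine Cxcl12 had the lowest p of the named genes, at 357 ± 138 CPM in controls and 1723 ± 146 CPM in Sox17-deleted hypoxic libraries (log2 fold change 2.27, SE 0.33). The matrix glycoprotein gene Sparcl1 was at 698 ± 104 and 3860 ± 2471 CPM (2.47, SE 0.42). Calcrl, which encodes the receptor for adrenomedullin and calcitonin gene-related peptide, was lower, at 1477 ± 260 and 454 ± 79.2 CPM (−1.70, SE 0.30). Hilpda, whose product inhibits lipolysis at lipid droplets, was lower too, at 1848 ± 255 and 437 ± 169 CPM (−2.08, SE 0.36). Although lower here, Hilpda is in the list of hypoxia-inducible factor (HIF) target genes, of which 17 of 27 tested were higher. For each of these 4 genes all libraries of a group lay on the same side of all libraries of the other. The edgeR adjusted p was 0.0698 for Cxcl12 and 0.119 for Sparcl1, Calcrl and Hilpda, so none passed over all 8282 genes tested. Restricted to the 1641 genes with a mean of at least 128 CPM, a choice made after seeing the data, these were the 4 genes that edgeR called, each with an adjusted p of 0.0229; over 18 alternatives the adjusted p ran from 1.60e-10 to 0.676 for Cxcl12 and from 7.82e-06 to 0.676 for Hilpda.

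The other named genes reported here had edgeR adjusted p values between 0.211 and 0.346. Higher in the Sox17-deleted hypoxic libraries were the cytoskeletal genes Myh9 (325 ± 57.3 and 2374 ± 1774 CPM) and Myh14 (56.9 ± 43.0 and 920 ± 918 CPM). The groups overlapped for Myh14, and its log2 fold change of 4.01 was 3.11 without Sox17-deleted hypoxic library 4. Gsn, which encodes the actin-severing protein gelsolin, stood at 324 ± 97.2 and 2657 ± 3623 CPM, and its log2 fold change of 3.03 was 1.40 without Sox17-deleted hypoxic library 4. Elastin (Eln) was at 186 ± 52.2 and 521 ± 100 CPM, annexin A2 (Anxa2) at 712 ± 114 and 1824 ± 820 CPM, and Bnip3, a mitophagy receptor induced by hypoxia, at 73.6 ± 42.7 and 305 ± 111 CPM. Mgll, the monoacylglycerol lipase gene, had 524 ± 137 and 1365 ± 373 CPM, the carbonyl reductase gene Cbr2 730 ± 87.4 and 1782 ± 568 CPM, and Nucks1 365 ± 61.4 and 806 ± 147 CPM. Sftpc, Sftpd, Scgb1a1, Hsp90ab1 and Rplp2, also higher, are given with their lists. Lower were Sepp1, which encodes selenoprotein P (1997 ± 430 and 476 ± 290 CPM), the endothelial lectin gene Clec14a (746 ± 130 and 267 ± 144 CPM) and Tmem204 (804 ± 125 and 273 ± 161 CPM). Adgre5, an adhesion receptor gene, was at 800 ± 75.3 and 332 ± 79.9 CPM, and the homeobox gene Hoxa5 at 513 ± 120 and 189 ± 54.2 CPM.

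**Figure D2:**
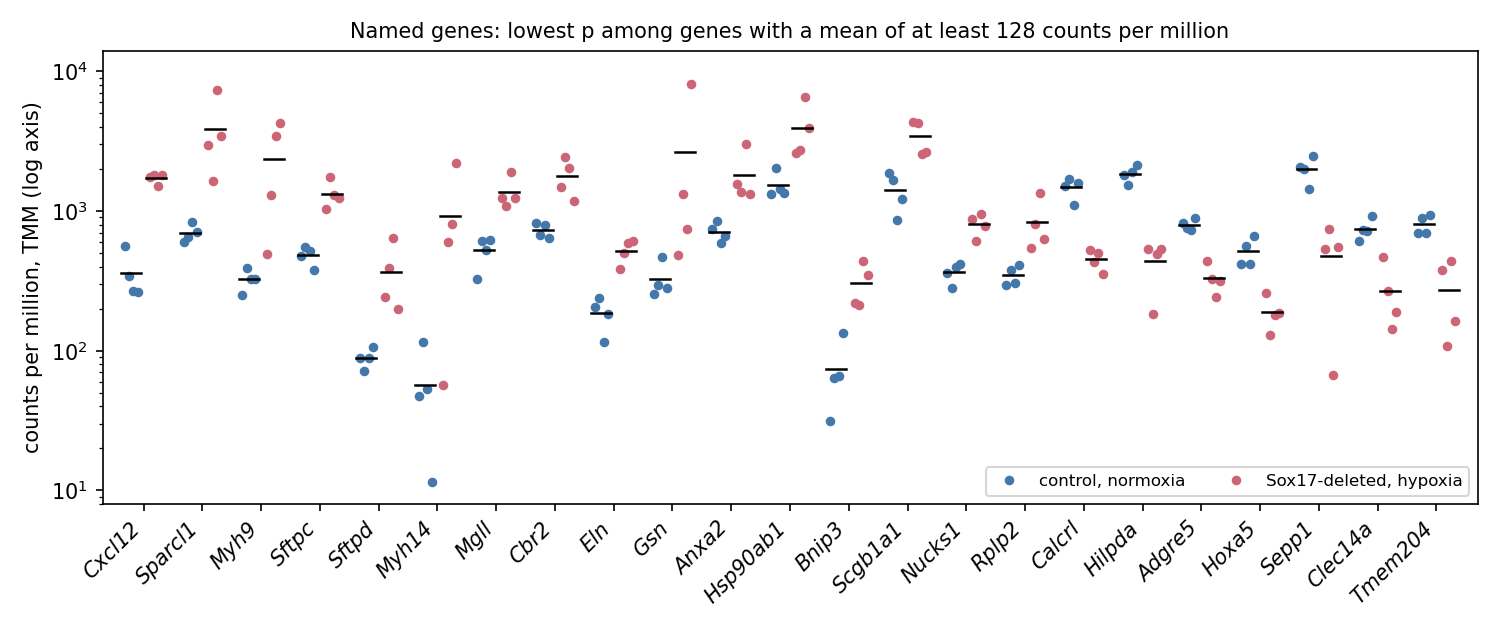
CPM (TMM-scaled, log axis) of the named genes in each library, control normoxia in blue and Sox17-deleted hypoxia in red; points are libraries and lines group means (n = 4). The groups do not overlap for any gene but Myh14, whose lowest Sox17-deleted hypoxic library lies within the control range.

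Over all genes, 0 of 8282 passed an edgeR adjusted p of 0.05. In this main fit an unadjusted p under 0.05 was found for 424 genes, where chance alone gives 414.1. That number depended on the setting. It was 435 with RLE and 412 with upper-quartile factors, but 851 of the same 8282 genes with limma-voom. DESeq2 gave 606 of 7974 filtered genes, and edgeR 217 of the 1641 genes with a mean of at least 128 CPM. With a library left out it ran from 381 (control library 4) to 973 (Sox17-deleted hypoxic library 1). DESeq2 called 469 genes (122 higher, 347 lower), 155 when given the same filtered genes (33 higher, 122 lower), and limma-voom with sample quality weights called 14 (9 higher, 5 lower). EdgeR called 17 without a low-count filter (10 higher, 7 lower), 4 among genes with a mean of at least 128 CPM (2 higher, 2 lower), 1 with robust estimation (higher), and 5 without Sox17-deleted hypoxic library 1 (Cxcl12 and Myh9 higher, Cx3cl1, Serinc3 and Sox17 lower). Of the 469 DESeq2 genes, 153 had a group with 0 counts in all 4 libraries and 207 had a library with 0 or 1 count in the higher group. The groups did not overlap for 539 of the 8282 genes, 131 higher and 408 lower, or 6.51% where chance gives 2.86%. Among the 1641 genes with a mean of at least 128 CPM, 155 did not overlap (9.45%), with 76 higher and 79 lower. Fewer genes were detected in the Sox17-deleted hypoxic libraries, and its part in the larger number of lower genes over all tested genes was not tested.

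General capillary markers, which characterise the endothelial cells that line most of the alveolar capillary bed, fell as a list in the Sox17-deleted hypoxic libraries: 12 of 13 tested members were lower (median log2 fold change −0.83, camera adjusted p = 0.00131). With an estimated correlation the camera adjusted p was 0.389, and without Sox17-deleted hypoxic library 4 it was 0.109. In the main edgeR test no member passed over all genes and 2 did adjusted over the list alone, Hilpda and Plvap, the gene of the fenestral diaphragm protein, at 942 ± 281 and 259 ± 210 CPM. Other members, none past the test, included Cd93 (3531 ± 574 and 1989 ± 1042 CPM), the lipoprotein lipase gene Lpl (1359 ± 477 and 633 ± 553 CPM) and Gpihbp1, which anchors that lipase to capillary walls (1224 ± 232 and 1136 ± 366 CPM). The summed level of the list was 14380 ± 820 and 7697 ± 3152 CPM (exact permutation p = 0.0286, adjusted p = 0.133 over 42 lists). Fewer genes were detected in the same libraries, and their alveolar type 2 markers summed to 2944 ± 838 CPM against 1200 ± 221 CPM.

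The other endothelial lists did not pass camera. Pan-endothelial markers (23 tested, camera adjusted p = 0.799) summed to 18030 ± 688 CPM in controls and 16890 ± 3891 CPM in Sox17-deleted hypoxic libraries. Camera adjusted p values were 0.192 for aerocyte capillary, 0.954 for venous and 0.613 for lymphatic markers. Of 22 arterial markers (camera adjusted p = 0.565) none passed the main edgeR test over all genes and 5 did adjusted over the list alone, in both directions. Cxcl12 and Eln were higher, and Sox17, Efnb2 and Bmx lower. Efnb2, which encodes the arterial ligand ephrin-B2, was at 214 ± 101 and 65.4 ± 27.8 CPM, and Bmx, a kinase gene of arterial endothelium, had 26, 545, 13 and 657 counts in the controls and 0 in all 4 Sox17-deleted hypoxic libraries.

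Cytosolic ribosomal protein genes rose as a list, with 50 of 58 members higher (median log2 fold change 0.49, camera adjusted p = 4.50e-09). With an estimated correlation the camera adjusted p was 0.101. In the main edgeR test no member passed, either over all genes or adjusted over the list alone. Rplp2 was at 347 ± 55.6 and 837 ± 365 CPM, Rpl14 at 286 ± 72.9 and 643 ± 177 CPM and Rpl13a at 261 ± 55.5 and 525 ± 140 CPM, and the list summed to 11950 ± 588 and 17750 ± 3697 CPM (exact permutation p = 0.0286, adjusted p = 0.133 over 42 lists). Ribosomal protein genes share sequence with many processed pseudogenes, so their counts are uncertain. Heat shock and chaperone genes rose as well (9 of 11 higher, median 0.54, camera adjusted p = 0.00501, and adjusted p = 0.119 with an estimated correlation). The list missed the threshold among genes with a mean of at least 128 CPM (camera adjusted p = 0.162) and without its 2 most abundant members (0.0510), both chosen after seeing the data. Hsp90ab1, a constitutive cytosolic chaperone gene, passed adjusted over the list alone at 1534 ± 329 and 3958 ± 1810 CPM, while Hspa8 had 548 ± 143 and 607 ± 168 CPM. Both lists moved in libraries that also had fewer genes detected and higher epithelial markers.

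MHC class II genes, which present antigen and are transcribed in antigen-presenting cells and some capillary endothelium, rose with 6 of 7 members higher (median 0.98, camera adjusted p = 0.000155, and adjusted p = 0.126 with an estimated correlation). Cd74, the invariant chain gene, was at 561 ± 221 and 1440 ± 676 CPM and H2-Ab1 at 417 ± 140 and 847 ± 269 CPM. In the main edgeR test both were past the threshold adjusted over the list alone and neither over all genes. Macrophage and monocyte markers, another source of these transcripts, summed to 279 ± 43.2 and 457 ± 156 CPM (exact permutation p = 0.0286, adjusted p = 0.133) and did not pass camera (adjusted p = 0.485). Alveolar type 2 cells can carry MHC class II as well, and their markers were higher in the same libraries, which had fewer genes detected.

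Among markers of other lung cell types, epithelial and fibroblast lists rose and the erythroid list fell. Alveolar type 2 markers had 11 of 13 members higher (median 1.42, camera adjusted p = 6.89e-05, and adjusted p = 0.105 with an estimated correlation). The surfactant protein genes Sftpc (482 ± 73.7 and 1333 ± 296 CPM) and Sftpd (88.8 ± 14.0 and 367 ± 199 CPM) passed adjusted over the list alone. Markers of the club and ciliated epithelial list had 7 of 7 members higher (median 0.97, camera adjusted p = 0.00320, and adjusted p = 0.119 with an estimated correlation). Their call rests on few genes: Scgb1a1, the club cell secretory protein gene, was at 1413 ± 460 and 3440 ± 975 CPM and passed adjusted over the list alone, and the list missed the threshold without control library 2 (camera adjusted p = 0.167) and without any 1 of the 4 Sox17-deleted hypoxic libraries (0.0575, 0.281, 0.0600 and 0.0812). Fibroblast markers had 12 of 16 members higher (median 1.40, camera adjusted p = 0.00113, and adjusted p = 0.304 with an estimated correlation), with Gsn past the threshold adjusted over the list alone, Col1a2 at 108 ± 99.6 and 315 ± 242 CPM, and Col1a1 at 37.6 ± 32.6 and 8.59 ± 8.58 CPM. Among genes with a mean of at least 128 CPM the camera adjusted p was 0.0579 for the fibroblast list and 0.0803 for the erythroid list. The erythroid list had 7 of 7 members lower (median −0.90, camera adjusted p = 0.00659), and the adjusted p was 0.506 with an estimated correlation. Hba-a1 was at 1546 ± 456 and 914 ± 822 CPM, the globin genes share reads, and camera gave an adjusted p of 0.0992 without Sox17-deleted hypoxic library 3 and 0.280 without library 4.

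**Figure D3:**
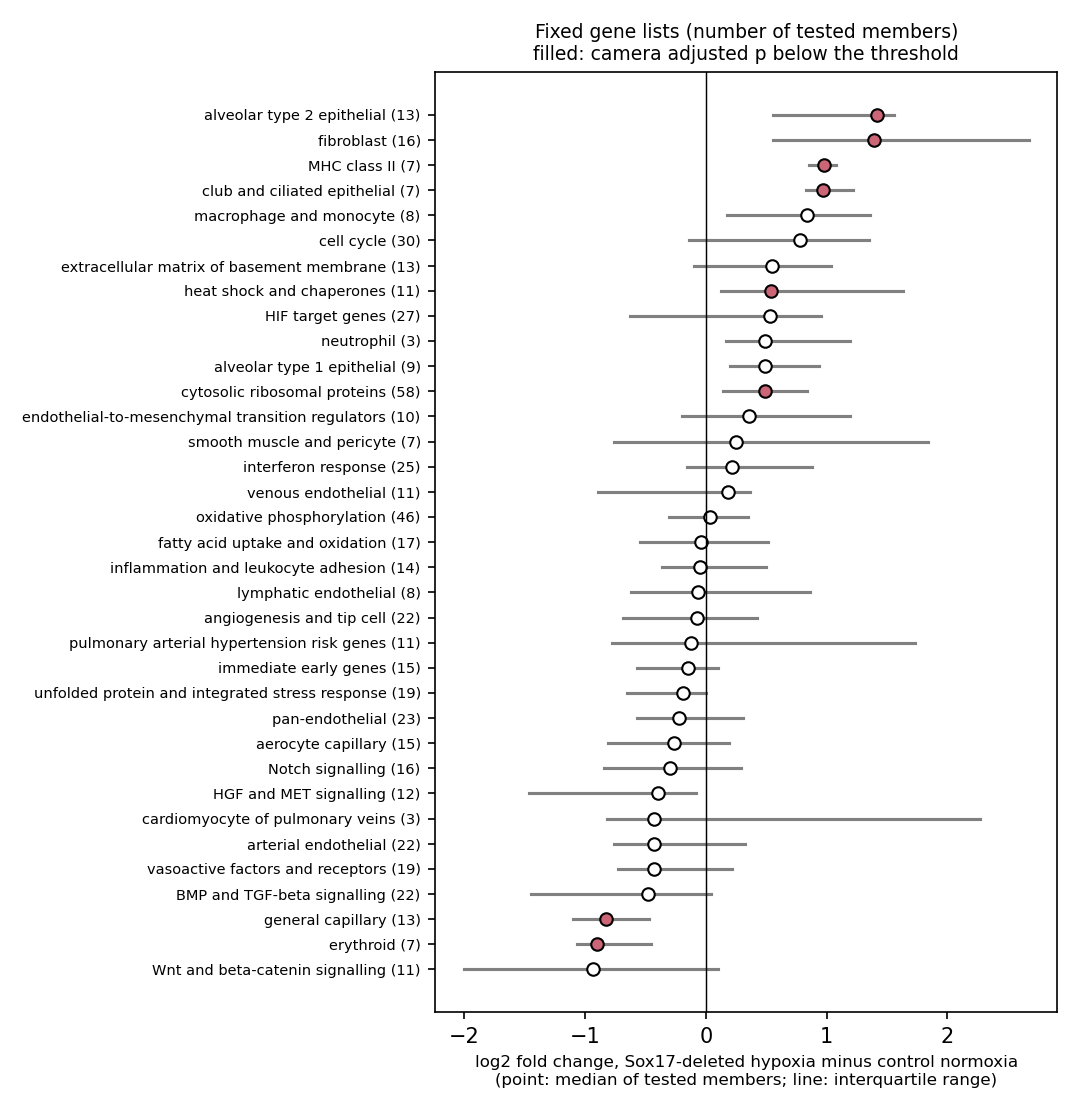
Median log2 fold change (Sox17-deleted hypoxia minus control normoxia) of the tested members of each of the 35 tested lists, with the interquartile range as a line and the number of tested members in parentheses; filled points passed camera at the preset correlation. The 6 lists that rose and the 2 that fell have medians from 0.49 to 1.42 and of −0.83 and −0.90. None of these lists passed camera with an estimated correlation.

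Camera adjusted p values just above the threshold, 0.0502 in each case, belonged to alveolar type 1 markers (8 of 9 higher), cell cycle genes (22 of 30 higher) and BMP and TGF-beta signalling (16 of 22 lower). Over the alternatives, the adjusted p ran from 0.000934 to 0.355 for alveolar type 1 markers (past the threshold in 6 of 16), from 0.00613 to 0.745 for cell cycle genes (4 of 17) and from 0.0134 to 0.220 for BMP and TGF-beta signalling (8 of 17). With an estimated correlation the camera adjusted p was 0.304, 0.389 and 0.220 in turn. Alveolar type 1 markers included Ager at 178 ± 7.36 and 342 ± 82.6 CPM and the most abundant member Hopx at 309 ± 54.7 and 332 ± 133 CPM. In BMP and TGF-beta signalling, the receptor gene Bmpr2, mutated in heritable pulmonary arterial hypertension, was at 1033 ± 383 and 552 ± 232 CPM, and Eng, which encodes the co-receptor endoglin, at 460 ± 98.7 and 199 ± 114 CPM. The rotation test fry, which asks whether members move on balance in a direction, gave an adjusted p of 0.0157 for this list, 0.0355 for HGF and MET signalling (9 of 12 lower, camera adjusted p = 0.125, and adjusted p = 0.304 with an estimated correlation) and 0.0355 for ribosomal proteins, the only list called by camera that also passed fry. The 12 HGF and MET genes tested do not include Hgf and Met, and these lists, too, moved in libraries with fewer genes detected and higher epithelial markers. HIF target genes did not pass camera (17 of 27 higher, adjusted p = 0.352). Adjusted over the list alone, Bnip3 passed as higher and Hilpda as lower.

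The remaining pathway lists did not pass camera, with adjusted p values of 0.125 for Wnt and beta-catenin signalling, 0.180 for basement membrane, 0.323 for endothelial-to-mesenchymal transition regulators, 0.401 for vasoactive factors and receptors, 0.492 for Notch signalling, 0.50 for immediate early genes, 0.549 each for interferon response, oxidative phosphorylation and pulmonary arterial hypertension risk genes, 0.799 for angiogenesis and tip cell genes, 0.871 each for inflammation and fatty acid oxidation, and 0.901 for the unfolded protein response. Smooth muscle and pericyte (0.492), cardiomyocyte (0.50) and neutrophil (0.559) markers did not pass camera either. Their most abundant members were Myh11 (27.2 ± 27.5 and 192 ± 213 CPM), Myh6 (4.32 ± 5.51 and 136 ± 135 CPM) and S100a9 (56.0 ± 23.3 and 78.9 ± 63.2 CPM). The most abundant macrophage and monocyte marker, Ly6c2, was at 141 ± 35.7 and 131 ± 75 CPM. Lists with fewer than 3 tested members were not tested, and their most abundant members were Gzma for T and NK cells (0.687 ± 0.887 and 28.3 ± 34.7 CPM), Jchain for B and plasma cells (26.7 ± 31.2 and 58.7 ± 85.7 CPM), Gpm6a for mesothelium (11.3 ± 17 and 8.88 ± 7.25 CPM), Nrgn for platelets (24.2 ± 29.6 and 1.36 ± 2.66 CPM) and Scn7a for Schwann cells and neurons (308 ± 46.2 and 593 ± 183 CPM). As a check of the animals, Xist lay between 20.4 and 153 CPM in every library. For 7 lists, none of them called, the median, the mean and the camera direction differed in sign: venous, lymphatic, hypertension risk, inflammation, fatty acid oxidation, oxidative phosphorylation and cardiomyocyte.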

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

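Of the tests in this part, the restriction to genes with a mean of at least 128 CPM and DESeq2 on the filtered genes were chosen only after the result was seen. Within each group of 4 libraries, the highest or lowest value of Sox17, Hgf, Met, the 24 named genes and the library measures was compared with the gap to its nearest neighbour (Dixon's test at 95%). Of 64 groups checked, 6 had a value that far from the others, and all 6 were Sox17-deleted hypoxic. Chance gives about 3.2 for normally distributed values. The CPM were not transformed and come from the same libraries, so 6 is not shown to be an excess. Sox17 was at 37.8 CPM in library 1 and 0.973 to 3.61 CPM in the other 3 libraries. Hgf was at 54.1 CPM in library 2 and 0 in the others, and Met was at 21.9 CPM in library 4 and 0 to 0.324 CPM in the others. Hilpda was lowest in library 2, at 184 CPM against 495 to 535 CPM. Gsn was at 8065 CPM in library 4 and 484 to 1334 CPM in the others. Anxa2 was at 3045 CPM in library 3 and 1322 to 1564 CPM in the others.

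Whether chance alone gives the counts of calls was checked with all 35 splits of the 8 libraries into 4 and 4. For the edgeR count over all tested genes chance cannot be told apart: a count of 0 is matched by any split (35 of the 35), so the splits decide nothing there. For 4 other counts only the real split, 1 of the 35, reached the value, which is the smallest share that 35 splits allow. These were 4 genes with a mean of at least 128 CPM (highest other split 0), 14 genes with limma-voom (highest other 1), 155 genes with DESeq2 on the filtered genes (highest other 42), and 539 genes whose groups do not overlap (highest other 333). The 4 counts come from the same 8 libraries and are not separate tests, so they argue against chance without excluding it. The real split also parts the libraries by genes with at least 1 count (10081 ± 259 in controls and 8450 ± 305 in Sox17-deleted hypoxic libraries). The splits cannot tell a difference in detection from a difference in expression. For the 8 gene lists called by camera the splits did not argue against chance: 2 of the 35 splits gave as many, and the highest other split, which exchanged control library 2 with Sox17-deleted hypoxic library 1, gave 9.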

How the results depend on the processing

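All 25 tested named genes and all 8 called lists kept their direction in every alternative that gave a value. These lists, and all of these genes but Sox17, were chosen for low p in the same libraries, so a kept direction is weak support. The edgeR count of 0 genes was unchanged with RLE factors, upper-quartile factors, the stricter filter, an added 2-fold minimum and the replicate block. It was 17 without a low-count filter, 4 at a mean of at least 128 CPM (fewer genes tested), 1 with robust estimation, 469 with DESeq2, 155 with DESeq2 on the filtered genes and 14 with limma-voom, and 0 to 5 with a library left out. Sox17 passed at a log2 fold change of −4.38 without a filter, −4.35 with DESeq2 and −4.35 with DESeq2 on the filtered genes. It did not pass at −5.54 with limma-voom (adjusted p = 0.334) or −5.75 with the replicate block (0.0937), and lay between −6.51 and −4.00 with a library left out. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at −0.0269 to 0.0214 and 2 of 4 libraries correlated best with their own number. With the replicate block edgeR called 0 genes and camera 9 lists, and no call was lost. The number of called lists, 8 in the main test, was 0 with an estimated correlation, 3 with fry (ribosomal proteins, plus BMP and TGF-beta and HGF and MET signalling, which camera did not call), 11 with upper-quartile factors and 5 to 10 with a library left out. Camera adjusted p values with an estimated correlation were 0.389 (general capillary), 0.126 (MHC class II), 0.101 (ribosomal), 0.119 (heat shock), 0.105 (alveolar type 2), 0.119 (club and ciliated), 0.304 (fibroblast) and 0.506 (erythroid). The adjusted p by fry was 0.0654 for general capillary, MHC class II, heat shock, alveolar type 2 and club and ciliated lists, 0.255 for fibroblast and 0.242 for erythroid. At a mean of at least 128 CPM, heat shock (0.162), fibroblast (0.0579) and erythroid (0.0803) lists missed the threshold, as did club and ciliated epithelial without a filter (0.0759). Without their 2 most abundant members, heat shock (0.0510) and club and ciliated (0.109) lists missed it. With a library left out the ranges were 9.83e-05 to 0.109 for general capillary, 0.00151 to 0.281 for club and ciliated epithelial and 9.00e-06 to 0.280 for erythroid. Lists that were not called reversed direction, with these adjusted p values: pan-endothelial and venous endothelial with RLE factors (0.996) and the replicate block (0.939); arterial endothelial (0.658), angiogenesis (0.755), inflammation (0.755), unfolded protein (0.832) and oxidative phosphorylation (0.849) at a mean of at least 128 CPM; lymphatic and HIF (0.697), inflammation and interferon (0.487) and oxidative phosphorylation (0.255) with fry; inflammation, fatty acid and smooth muscle lists (0.914) without 2 members. With a library left out, lists that reversed spanned 0.532 to 0.927 (pan-endothelial), 0.352 to 0.987 (arterial endothelial), 0.786 to 0.927 (venous endothelial), 0.216 to 0.994 (pulmonary arterial hypertension risk genes), 0.593 to 0.979 (angiogenesis and tip cell), 0.583 to 0.994 (inflammation and leukocyte adhesion), 0.677 to 0.979 (unfolded protein and integrated stress response), 0.513 to 0.979 (fatty acid uptake and oxidation) and 0.547 to 0.927 (neutrophil). Beyond the smaller gene or library number of some settings, the cause was not tested. At a mean of 10 to 20 CPM in the other 7 libraries, 28.9% of values in control libraries and 53.0% in Sox17-deleted hypoxic libraries were 0 or 1 count, for a reason that was not tested.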

Other observations

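Of the tests in this part, the restriction to well measured genes, the lists without their 2 most abundant members and the comparison of epithelial with erythroid markers were chosen only after the result was seen. Restricted to genes with a mean of at least 128 CPM, camera called 3 lists as lower that it did not call over all genes: vasoactive factors and receptors (adjusted p = 0.0134), BMP and TGF-beta signalling (adjusted p = 0.0134) and aerocyte capillary (adjusted p = 0.0241). Over their 17 alternatives, the adjusted p ran from 0.0134 to 0.748, from 0.0134 to 0.220 and from 0.0241 to 0.692. Over all genes, an estimated correlation gave 0.633, 0.220 and 0.646, and none was computed on the restricted genes. The same libraries had fewer genes detected and higher epithelial markers. Ramp2, which encodes the partner of the Calcrl receptor for adrenomedullin, was at 4440 ± 249 CPM in controls and 3298 ± 787 CPM in Sox17-deleted hypoxic libraries, lower in 4 of 4. The aerocyte markers Cyp4b1 (945 ± 105 and 307 ± 300 CPM) and Fibin (518 ± 198 and 134 ± 127 CPM) were lower in 4 of 4 libraries, while Car4, the carbonic anhydrase of aerocytes, was at 1026 ± 134 and 1021 ± 421 CPM.

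Sox17-deleted hypoxic library 1, with 37.8 CPM of Sox17, also had the highest summed general capillary markers of its group, 12174 CPM. The other 3 libraries of the group had 6734, 7096 and 4784 CPM of these markers, and the controls 13949, 13901, 14073 and 15607 CPM. A relation between Sox17 and these markers was not tested.

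Transcripts of epithelial and fibroblast genes were higher in the Sox17-deleted hypoxic libraries, although the tag was placed on endothelial ribosomes. With an estimated correlation the camera adjusted p was 0.105 for alveolar type 2, 0.119 for club and ciliated and 0.304 for fibroblast markers. In every control library as well, 10 of 15 alveolar type 2, 6 of 18 club and ciliated and 11 of 20 fibroblast markers had counts. More RNA carried over from all other lung cells, as the only change, would raise every cell type alike. The log2 ratio of epithelial to erythroid marker counts was 0.75 ± 0.44 in controls and 3.29 ± 1.45 in Sox17-deleted hypoxic libraries, a difference of 2.54 (exact permutation p = 0.0286). This ratio cannot decide the question, because it pairs lists already seen to rise and to fall in these libraries. Summed erythroid markers alone were at 2119 ± 476 CPM in controls and 1309 ± 1410 CPM in Sox17-deleted hypoxic libraries (exact permutation p = 0.314). A few very abundant transcripts as the source cannot be told apart in full, since 2 of the 3 lists passed camera without their 2 most abundant members and the club and ciliated list did not. More carry-over, from all other lung cells or of epithelial and fibroblast RNA alone, stays open as an explanation. So do less blood left in the lungs, with or without more carry-over, and a change in these cells with Sox17 loss or hypoxia, both untested. In each case the higher Sftpc and Scgb1a1 levels may not be endothelial. The same holds for other higher genes, among them the fibroblast marker Gsn.

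Ribosomal protein genes were higher as a list in the Sox17-deleted hypoxic libraries, with short transcripts (median length 992 nucleotides against 3161 for other genes). Length and GC content were those of the longest annotated transcript of each gene, protein-coding where there is such a transcript. The trend with this annotated length and GC content does not account for the whole difference. With the trend over 7965 genes removed, the median log2 fold change was 0.33 (0.326) in place of 0.49, or 66.9% of it. The transcripts sequenced can differ from the longest annotated ones, so an effect of their own length or GC content stays open. The median lay at percentile 100 of 10000 random lists matched on mean expression, which argues against loss of less abundant transcripts alone. Random lists do not keep the correlation between ribosomal protein genes, so this percentile overstates the certainty. Reads shared with processed pseudogenes were not tested, and the camera adjusted p was 0.101 with an estimated correlation. A change in these genes with Sox17 loss or hypoxia stays open and was not tested.

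Of 6111 genes with at least 10 counts in every control library, 84 had 0 or 1 count in every Sox17-deleted hypoxic library, among them Arid2 (200, 571, 1194 and 890 counts in controls), Cant1 and Bmx. Independent loss in each library at matched abundance would give 24.9, a ratio of 3.37 (95% interval 2.69 to 4.17), but lower library complexity cannot be told apart as the source, because the reverse comparison rests on 1 gene (Gdpd3). The interval treats genes as independent and is too narrow where they are not. Hoxa3 and Hoxaas2 had the same counts in every library, as did Ccdc22 and Foxp3. None of the 2064 such genes with a control mean of at least 100 CPM was lost (0 of 2064), and the highest control mean among the lost genes was 62 CPM. GC content of the 3′ end of the longest annotated transcript was compared for 80 of the 84 lost genes. Their median differed from that of matched genes by −0.6 percentage points (43.3% and 43.9%, permutation p = 0.637). No shift to high or low GC was seen, but a bias against both extremes would leave the median in place and was not tested. Regulation by Sox17 loss or hypoxia of some of these genes stays open and was not tested apart from detection.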
